A study of Homo sapiens with 12 samples.

How the data were processed

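Total RNA of EA.hy 926 cells was labelled with biotin and hybridised to 1 array per culture, per the labels' protocols. The labels name 2 media, 2 treatments and biological replicates 1 to 3, and these labels alone set the groups. The deposited values are log2 expression per probe set, for 33297 probe sets on 12 arrays. The submitters' processing notes name RMA, which corrects background, quantile-normalizes arrays and summarises probes, and Partek 6.5, with no role or order. The genome build and any probe filter are not given in the sources used here. On every array the deposited log2 values ran from at least 2.77 to at most 14.5, array medians lay between 7.25 and 7.33, and correlations between arrays from 0.987 to 0.997. No array pair was identical. No detection values or scanner intensities were used here, so dim probe sets could not be told from background.

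The probe table supplied with the values lists 21214 of the probe sets. Of these 19460 have 1 gene symbol, 1754 several and 0 none, and the other 12083 are unnamed here. RefSeq gene names (assembly GRCh38.p14) matched 19429 symbols by Entrez ID and changed 0. Each gene was represented by its probe set with the highest mean over all arrays among those with 1 symbol, which gave 18417 genes, 769 of them with more than 1 probe set. No filter on dim genes was applied. Dihydrofolate reductase was not analysed here.

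The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean for each of the 4 groups over all 12 arrays, which leaves 8 residual degrees of freedom. The contrasts were MTX minus control in each medium and averaged, Lo minus Hi in control and in MTX-treated cells, and their interaction. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values in the text are log2 changes ± SE from this model, and every adjusted p of a gene is limma's. The design, 24 gene lists, the rule for naming genes and most other settings were set before the data were examined. The lists held 663 symbols, of which 611 were measured. They were tested with camera (preset correlation 0.01) in each comparison except the average, with adjustment over 120 tests, and again with an estimated correlation and with fry. Of the 9 calls for MTX in Hi cells and the 10 in Lo cells, 0 held with an estimated correlation, and 8 and 8 passed fry, which tests whether a list's genes move one way and does not compare them with other genes.

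The named genes were, per comparison, the 5 largest rises and falls among called genes whose replicates did not overlap. To these were added up to 3 called members with the smallest p of each list that passed camera and 1 of each other list. For MTX in each medium and Lo minus Hi in control cells a fixed set was always named: TYMS, SLC19A1, FPGS, CDKN1A, IL6, CXCL8, CCL2, ICAM1, VCAM1, SELE and PTGS2, besides dihydrofolate reductase. Genes outside this rule, among them the other called members of lists with few calls, were chosen after their values were seen.

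Whether replicate numbers pair the arrays was checked by correlating deviations from group means across genes. For control and MTX arrays of the same number the correlations were 0.613, 0.474 and 0.703 in Hi cells and 0.427, 0.636 and 0.688 in Lo cells. The highest correlation between different numbers was 0.286 in Hi and 0.269 in Lo cells. The numbers were therefore taken to pair arrays within a medium, and a fit with a term for each medium and replicate number (4 residual degrees of freedom) is the paired fit. The shift of the replicate 3 arrays described under Results can also raise same-number correlations, and its part was not separated. This pairing comes from the data and not from a statement in the labels. Between media all same-number correlations were below 0, and those of different numbers reached 0.618.

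The analysis was tested on simulated data with the real means and spreads of the 18417 genes and 200 genes changed for MTX in Hi cells. It recovered 64.2% of 67 genes changed 1.5-fold, 97.0% of 66 changed 2-fold and 100% of 67 changed 4-fold, with 6 false calls. The paired fit recovered 50.7%, 95.5% and 100%, with 10 false calls. The simulated arrays were independent with no effect of pairs, so this does not show how the paired fit performs on paired arrays. A shift of 0.5 on the log2 scale given to the p53 target list was called by camera (adjusted p = 8.15e-52). The simulated genes were independent too, so this does not test camera on lists of correlated genes.

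Other settings, chosen in advance, were the replicate number as a block over all groups, further quantile normalization, subtraction of array medians, limits on dim genes (one kept only the genes brighter than the median gene, here the brighter genes), all probe sets or their mean, an intensity trend or no moderation in the spread, only the compared groups, array weights, a stricter threshold, a fold minimum and leaving out each array. The paired fit and the fits without all arrays of 1 replicate number were added after the data were seen.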

Results

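Gene expression was measured on 12 single-colour whole-transcript arrays of EA.hy 926 cells, a human line made by fusing umbilical vein endothelial cells with a lung carcinoma line. Cells labelled Hi grew in Medium 199 with 9 µM (4 mg/L) folic acid added, the usual supply for this line. Cells labelled Lo had been adapted to the same medium with no added folic acid, which holds 23 nM. Confluent cultures received vehicle (control) or 0.5 µM methotrexate (MTX), an antifolate that inhibits dihydrofolate reductase, for 48 hours. Each of the 4 groups, Hi control, Hi MTX, Lo control and Lo MTX, had 3 arrays that the labels call biological replicates. The comparisons ask what MTX changed in each medium, what the low folate supply changed with and without MTX, and whether the MTX effect depended on the medium. The values were log2 expression, and 18417 genes were tested. The median over all probe sets lay between 7.25 and 7.33 on every array, and the number of arrays limits the precision.

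Control and MTX arrays separated in both media, while the media labels did not separate consistently. The first 2 principal components held 48.1% and 25% of the variance. In each treatment the array labelled Hi replicate 3 lay with the arrays labelled Lo replicates 1 and 2, and the array labelled Lo replicate 3 lay with the arrays labelled Hi replicates 1 and 2. VWF, the von Willebrand factor of endothelial cells, showed this on single arrays. Its log2 level was 9.71, 8.96 and 7.06 on the arrays labelled Hi control replicates 1, 2 and 3, and 7.03, 6.91 and 9.22 on those labelled Lo control. Groups were kept as labelled throughout, and each leading count is also given without the replicate 3 arrays, a choice made after the data were seen.

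**Figure D1:**
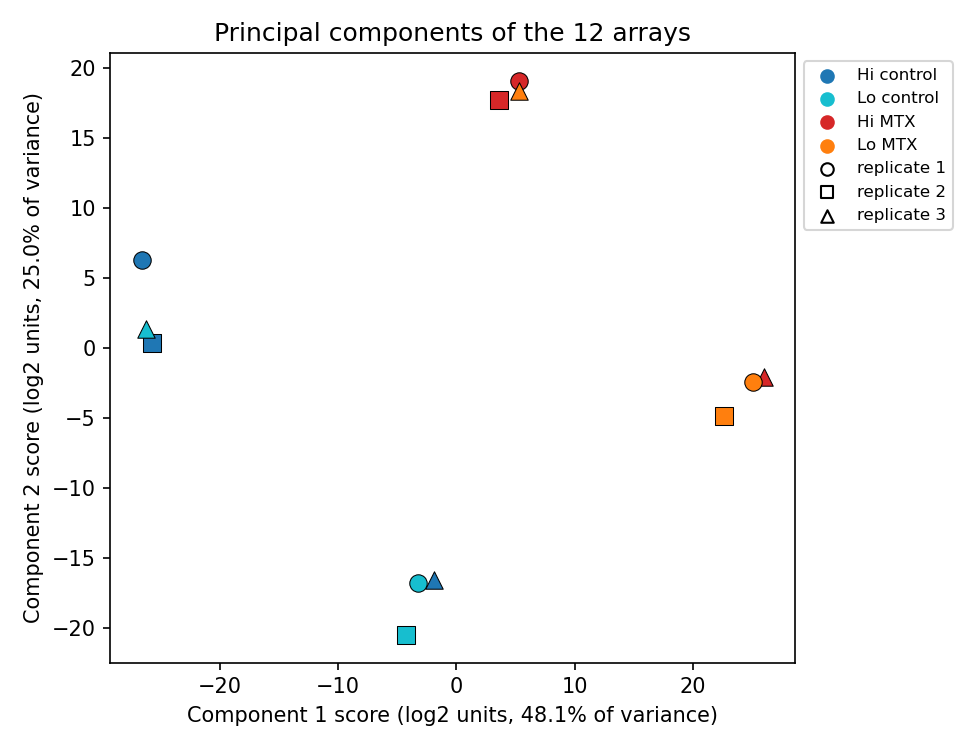
Scores of the 12 arrays on principal components 1 (48.1% of variance, x axis) and 2 (25%, y axis), computed from log2 expression, with 1 point per array, colour for the labelled group and shape for the replicate number. The triangles (replicate 3) of each medium label sit beside the circles and squares (replicates 1 and 2) of the other medium label.

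Genes lower with MTX in Hi cells included most measured genes of mitosis, and genes higher included p53 targets and some stress and inflammatory genes. By camera 5 of 24 lists were higher and 4 lower, and 0 of these 9 calls held with an estimated correlation (smallest adjusted p = 0.0657). The largest falls by the fixed rule were in PLK1, a mitotic kinase, 5.25-fold lower (log2 change -2.39 ± 0.13 SE, n = 3 per group, adjusted p = 5.56e-06), and H2BC14, a core histone, 4.98-fold lower (-2.32 ± 0.21, adjusted p = 0.000173). KIF20A, BUB1 and PRC1, which act in spindle function and cytokinesis, were 4.11-, 3.80- and 3.80-fold lower. The largest rises were in C3, the central complement component, 6.09-fold higher (2.61 ± 0.38, adjusted p = 0.00188), IL1RL1, the receptor of interleukin 33, 5.44-fold (2.44 ± 0.53, adjusted p = 0.0175), and DDIT3, a transcription factor of the integrated stress response, 5.10-fold (2.35 ± 0.26, adjusted p = 0.000361). SAT1, which acetylates spermidine and spermine, rose 4.47-fold and CXCL8, the neutrophil chemokine interleukin 8, 4.06-fold (2.02 ± 0.47, adjusted p = 0.0253). IL1RL1 was not called without Hi control replicate 1 or 2 or Hi MTX replicate 1 or 3 (adjusted p = 0.0729, 0.0848, 0.0534 and 0.0635). In all, 686 genes were higher and 543 lower with MTX, of which 45 and 80 differed at least 2-fold. Treating the MTX and control arrays of the same number as pairs gave 3864 genes (1934 higher, 1930 lower), and leaving out all arrays of replicate 3, 2 or 1 gave 2393 (1032 higher, 1361 lower), 30 and 225 genes. With array medians subtracted 805 were higher and 475 lower.

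Of 33 measured genes of mitosis and G2/M, 30 were lower and 0 higher in Hi cells (30 and 1 when adjusted over the list alone), with a median log2 change of -1.16. FOXM1, the transcription factor that drives many of them, was 2.40-fold lower (-1.26 ± 0.09, adjusted p = 7.1e-05). This list passed camera (adjusted p = 3.21e-40), with adjusted p = 0.0821 with an estimated correlation. In the paired fit the latter was 0.0306, adjusted over fewer tests. Of 35 genes of DNA replication and G1/S, 20 were lower (25, and 1 higher, when adjusted over the list alone), among them PRIM1, a primase subunit (2.31-fold lower), RFC4 of the clamp loader (1.73-fold) and CHAF1B of chromatin assembly (1.78-fold). The test gave adjusted p = 1.16e-20, and adjusted p = 0.0821 with an estimated correlation. Of 28 replication-dependent histone genes 10 were lower (15, and 1 higher, when adjusted over the list alone). They included H2BC3 (3.04-fold lower) and H1-3 (1.94-fold lower), and the list had adjusted p = 1.29e-08, and 0.134 as adjusted p with an estimated correlation. Near-identical histone genes can share probes, so single histone values are uncertain.

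Of 32 measured genes activated by p53, which follow DNA damage and nucleotide stress, 20 were higher in Hi cells and 0 lower (27 and 0 when adjusted over the list alone). SESN2 rose 2.21-fold (1.14 ± 0.12, adjusted p = 0.000275), the cell cycle inhibitor CDKN1A 1.72-fold (0.79 ± 0.09, adjusted p = 0.000372) and TRIAP1 1.60-fold. The list had adjusted p = 2.74e-25, and adjusted p = 0.0657 with an estimated correlation. In the ATF4 amino acid response 9 of 28 genes were higher (11, and 1 lower, when adjusted over the list alone), including CEBPB (2.57-fold) and the alanyl-tRNA synthetase AARS1 (1.49-fold) besides DDIT3. That list had adjusted p = 1.14e-06, and adjusted p = 0.0893 with an estimated correlation. Of 25 AP-1 and immediate early genes 6 were higher (9 when adjusted over the list alone), such as the phosphatase DUSP5 (1.70-fold) and the nuclear receptors NR4A1 (1.48-fold) and NR4A3 (1.46-fold). Their test gave adjusted p = 4.86e-08, and adjusted p = 0.0748 with an estimated correlation.

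Of 24 NF-kB feedback and target genes 7 were higher in Hi cells and 0 lower (10 and 0 when adjusted over the list alone), with NFKB2 at 2.09-fold (1.06 ± 0.15, adjusted p = 0.00141), TRAF1 at 2.59-fold (1.37 ± 0.19, adjusted p = 0.00157) and NFKBIB at 1.59-fold. The list had adjusted p = 4.25e-06, and adjusted p = 0.0657 with an estimated correlation. Of 33 cytokines and chemokines 6 were higher (7, and 1 lower, when adjusted over the list alone). These included IL11 (2.45-fold, 1.29 ± 0.17, adjusted p = 0.00125), IL32 (2.02-fold, 1.01 ± 0.14, adjusted p = 0.00131) and IL33 (1.89-fold, 0.92 ± 0.10, adjusted p = 0.000275), and the list had adjusted p = 0.00512, and adjusted p = 0.44 with an estimated correlation. ICAM1, which binds leukocyte integrins, was 1.71-fold higher (0.77 ± 0.18, adjusted p = 0.026). IL6 had a log2 change of 0.99 ± 0.34 (adjusted p = 0.128, paired adjusted p = 0.00294) and PTGS2, the inducible cyclooxygenase, 1.29 ± 0.36 (adjusted p = 0.0543, paired adjusted p = 0.00591). The log2 change of CCL2 was -0.43 ± 0.13 (adjusted p = 0.0763, paired adjusted p = 0.0346), and those of the adhesion molecules VCAM1 and SELE were 0.02 ± 0.07 and -0.01 ± 0.08 (adjusted p = 0.92 and 0.962). IL6 and PTGS2 passed without Hi control replicate 3 (adjusted p = 0.0142 and 0.00654), and PTGS2 without Lo control replicate 3 (0.0211). Without Hi control replicate 1, Hi MTX replicate 1 or Hi MTX replicate 2 the adjusted p was 0.101, 0.0639 and 0.0972 for CXCL8 and 0.0901, 0.0662 and 0.101 for ICAM1, and it was 0.1 for CXCL8 without Hi control replicate 2 and 0.0628 for ICAM1 without Hi control replicate 3.

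Of 26 endothelial markers measured in Hi cells 5 were lower (TEK, ERG, CD34, FLI1 and ICAM2), 0 higher and 21 not called. TEK, the angiopoietin receptor, was 1.56-fold lower (-0.64 ± 0.10, adjusted p = 0.00228), the transcription factor ERG 1.61-fold (-0.69 ± 0.12, adjusted p = 0.00687) and CD34 1.81-fold (-0.85 ± 0.17, adjusted p = 0.0123). The list had adjusted p = 0.00512, and did not pass with an estimated correlation (adjusted p = 0.963) or by fry (fry adjusted p = 0.472). The call was lost without Hi control replicate 1 (adjusted p = 0.116) or Hi MTX replicate 3 (0.135). This list also differed between the arrays that stood with the other medium label, as described for VWF. Genes of folate use did not move as a list (adjusted p = 1): of 27 measured, SHMT1, the cytosolic serine hydroxymethyltransferase, was 1.80-fold lower (-0.85 ± 0.11, adjusted p = 0.00122), GGH was lower and MTRR higher. TYMS, the thymidylate synthase, had a log2 change of -0.06 ± 0.13, the reduced folate carrier SLC19A1 0.02 ± 0.08 and FPGS, which adds glutamates to folates and MTX, 0.09 ± 0.07 (adjusted p = 0.904, 0.951 and 0.593).

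The other lists did not pass in Hi cells, and each had few members called. Purine and pyrimidine synthesis had adjusted p = 0.126, with RRM1 (1.60-fold lower), RRM2 and DUT lower among 26 genes, and passed without Hi control replicate 1 (0.017) or Hi MTX replicate 3 (0.00765). Among hypoxia genes (adjusted p = 0.052, paired 0.0174, and 0.0272, 0.0459 and 0.0366 without Hi MTX replicate 2, Lo control replicate 3 and Lo MTX replicate 3) NDRG1 was 1.65-fold higher, among adenosine genes (0.12) NT5E, the enzyme that makes extracellular adenosine, was 1.34-fold lower, and among leukocyte adhesion molecules (0.442) SELP was 1.59-fold lower. HMOX1 of the NRF2 list (0.911) was 1.81-fold higher, SYVN1 of the unfolded protein response (0.528) 1.28-fold, ULBP2 of antigen presentation (0.705) 1.68-fold and TRIM22 of the interferon list (0.809) 1.25-fold. Without Hi MTX replicate 3 the interferon list was lower (median -0.29, adjusted p = 0.0335). TRIM22 was not called without Hi control replicate 1 or 2 or Hi MTX replicate 1, 2 or 3 (0.115, 0.0851, 0.0557, 0.0766 and 0.12), SYVN1 without Hi control replicate 2 (0.0512), and THBS1 without Hi control replicate 2 or Hi MTX replicate 1 (0.0545 and 0.0587). PTGIS, the prostacyclin synthase, was 1.77-fold lower in the eicosanoid list (0.947), THBS1 1.29-fold lower in the mesenchymal list (0.488) and LYZ 1.89-fold lower in the leukocyte marker list (0.817), which served as a negative control. The adjusted p was 0.955 for coagulation and complement genes, 0.887 for cholesterol synthesis and 0.554 for epithelial markers of the fusion parent. For the folate, antigen presentation and eicosanoid lists the median, mean and test differed in sign. The count of genes for MTX in Hi cells was 788, 596, 769, 794 and 765 without Hi control replicate 1, Hi control replicate 2, and Hi MTX replicates 1, 2 and 3, respectively, and 785 when only the 6 Hi arrays entered the fit.

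**Figure D2:**
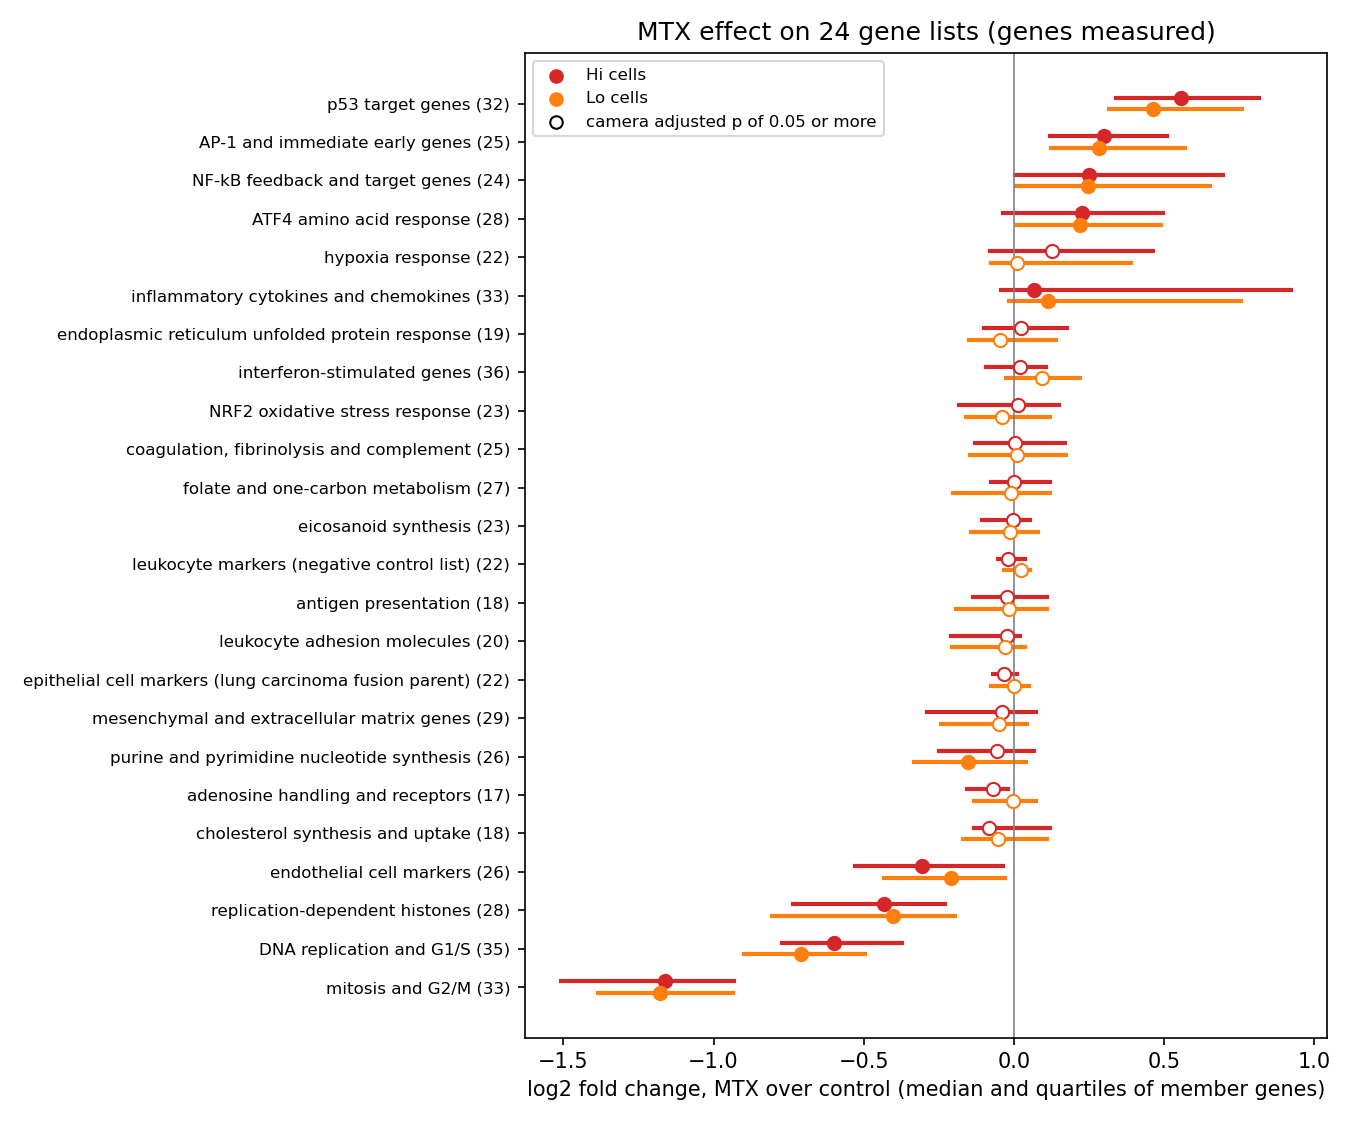
Log2 fold change of MTX over control (x axis) for 24 fixed gene lists (y axis, genes measured in parentheses), in cells labelled Hi (red) and Lo (orange). Points are medians over member genes, bars run between the quartiles, and open points mark lists with a camera adjusted p of 0.05 or more. Mitosis and G2/M genes lay lowest, with medians of -1.16 and -1.18, and p53 targets highest, with 0.56 and 0.46.

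Most measured genes of mitosis were also lower with MTX in Lo cells, and p53 targets and some stress and inflammatory genes were higher. By camera 5 of 24 lists were higher and 5 lower, and 0 of these 10 calls held with an estimated correlation (smallest adjusted p = 0.0657). PLK1 was 4.68-fold lower (-2.23 ± 0.13 SE, n = 3 per group, adjusted p = 1.24e-05), H2BC14 4.26-fold (-2.09 ± 0.21, adjusted p = 0.000208), the spindle motor KIF15 4.06-fold (-2.02 ± 0.21, adjusted p = 0.000247), PRC1 3.74-fold and BUB1 3.55-fold. DDIT3 was 4.59-fold higher (2.20 ± 0.26, adjusted p = 0.00044), C3 4.26-fold (2.09 ± 0.38, adjusted p = 0.00674), IL1RL1 4.16-fold (2.06 ± 0.53, adjusted p = 0.0399), SAT1 3.98-fold and TRAF1 3.43-fold (1.78 ± 0.19, adjusted p = 0.000311). IL1RL1 was not called without Hi MTX replicates 1 or 2, Lo control replicates 2 or 3 or Lo MTX replicates 1, 2 or 3 (adjusted p = 0.0577, 0.0567, 0.0552, 0.12, 0.121, 0.114 and 0.0738). In all, 611 genes were higher and 567 lower, of which 48 and 83 differed at least 2-fold. The paired fit gave 3745 genes (1824 higher, 1921 lower), and the fits without all arrays of replicate 3, 2 or 1 gave 2077 (1145 higher, 932 lower), 84 and 239. Subtracting array medians gave 659 higher and 529 lower. Without Lo control replicate 2, Lo MTX replicate 1 or Lo MTX replicate 2 the count was 750, 708 and 741.

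Among mitosis and G2/M genes 28 of 33 were lower in Lo cells (30 when adjusted over the list alone), with BIRC5, a spindle and survival protein, at 2.00-fold lower (adjusted p = 4.05e-05). The list had adjusted p = 1.19e-40, and adjusted p = 0.0821 with an estimated correlation (0.0306 in the paired fit, adjusted over fewer tests). DNA replication genes were lower in 23 of 35 cases (30 when adjusted over the list alone), led by RFC4 (2.23-fold), PRIM1 (2.67-fold) and the helicase subunit GINS2 (2.56-fold), with adjusted p = 2.19e-27, and adjusted p = 0.0657 with an estimated correlation. Of 28 histone genes 9 were lower (14, and 1 higher, when adjusted over the list alone), H1-3 by 1.81-fold and H2BC9 by 2.12-fold (adjusted p = 5.25e-09 for the list, and adjusted p = 0.128 with an estimated correlation). Purine and pyrimidine synthesis passed camera in Lo cells (adjusted p = 0.00191), but not with an estimated correlation (adjusted p = 0.869) or by fry (fry adjusted p = 0.359). There RRM1 (1.68-fold), RRM2 (2.20-fold), the subunits of ribonucleotide reductase, DUT (1.29-fold) and DTYMK were lower among 26 genes. That call was lost without Lo control replicate 2 (adjusted p = 0.0568) or Lo MTX replicate 3 (0.155), and that of DUT without Lo control replicate 2 (0.059) or 3 (0.0596).

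The p53 targets were higher in 19 of 32 cases in Lo cells (25 when adjusted over the list alone), with GADD45A at 2.32-fold (1.21 ± 0.14, adjusted p = 0.00036), SESN2 at 2.04-fold and CDKN1A at 1.70-fold. The list had adjusted p = 4.43e-21, and adjusted p = 0.0657 with an estimated correlation. In the ATF4 list 9 of 28 were higher (12 when adjusted over the list alone), ATF3 by 2.26-fold and CEBPB by 2.22-fold, with adjusted p = 1.1e-06, and adjusted p = 0.0893 with an estimated correlation. Of 25 AP-1 and immediate early genes 8 were higher (10 when adjusted over the list alone), with JUNB at 1.56-fold and DUSP5 at 1.62-fold (adjusted p = 4.4e-08 for the list, and adjusted p = 0.0748 with an estimated correlation). Of 24 NF-kB genes 7 were higher (11 when adjusted over the list alone), NFKB2 by 2.25-fold and NFKBIB by 1.62-fold (adjusted p = 6.44e-06 for the list, and adjusted p = 0.0657 with an estimated correlation). Of 33 cytokines and chemokines 7 were higher and CCL2 lower (10 and 1 when adjusted over the list alone), IL11 by 2.38-fold, IL32 by 2.15-fold and IL33 by 1.80-fold (adjusted p = 0.000378 for the list, and adjusted p = 0.242 with an estimated correlation).

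ICAM1 was 1.96-fold higher in Lo cells (0.97 ± 0.18, adjusted p = 0.00777), and CCL2 was 1.42-fold lower (-0.50 ± 0.13, adjusted p = 0.0402). CXCL8 had a log2 change of 1.59 ± 0.47 (adjusted p = 0.0745, paired adjusted p = 0.0481), IL6 of 0.74 ± 0.34 (adjusted p = 0.273, paired adjusted p = 0.012) and PTGS2 of 1.06 ± 0.36 (adjusted p = 0.115, paired adjusted p = 0.0147). VCAM1, SELE, TYMS, SLC19A1 and FPGS had log2 changes of -0.07 ± 0.07, 0.03 ± 0.08, -0.23 ± 0.13, -0.07 ± 0.08 and 0.07 ± 0.07, with adjusted p from 0.407 to 0.888. TEK (1.47-fold), ERG (1.44-fold), FLI1 (1.44-fold) and CD34 were lower among 26 endothelial markers. The endothelial list had adjusted p = 0.0192, and did not pass with an estimated correlation (adjusted p = 0.963) or by fry (fry adjusted p = 0.812). It was lost without Lo control replicate 3 (adjusted p = 0.237) or Lo MTX replicate 2 (0.148), and among the brighter genes (0.0514). ERG was not called without Lo control replicate 2 or 3 or Lo MTX replicate 1 or 2 (0.0576, 0.0995, 0.104 and 0.0806). FLI1 was not called without Hi control replicate 2, Hi MTX replicate 1, Lo control replicates 1, 2 or 3 or Lo MTX replicates 1 or 2 (0.0541, 0.062, 0.0661, 0.102, 0.151, 0.153 and 0.121). CCL2 was not called without Hi control replicate 1, Lo control replicates 1 or 2 or Lo MTX replicates 1, 2 or 3 (0.0561, 0.13, 0.145, 0.0954, 0.148 and 0.0605). Without Hi control replicate 3 CXCL8 (0.0441) and PTGS2 (0.0348) passed.

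The remaining lists did not pass in Lo cells. The adjusted p was 0.478 for folate genes, in which SHMT1 was 1.93-fold lower (-0.95 ± 0.11, adjusted p = 0.000532) and GGH was lower. It was 0.354 for adenosine genes, with NT5E 1.36-fold lower, and 0.354 for hypoxia genes, with NDRG1 1.60-fold higher. Leukocyte adhesion (0.412) had SELP 1.73-fold lower, antigen presentation (0.954) had TAP1 1.62-fold higher, and eicosanoid synthesis (0.705) had PTGIS 1.61-fold lower. The NRF2 list (0.947) had AKR1C3 1.35-fold lower, the unfolded protein list (0.887) SYVN1 1.28-fold higher, the mesenchymal list (0.494) THBS1 1.32-fold lower and the leukocyte marker list (0.992) LYZ 1.75-fold lower. The interferon (0.434), coagulation and complement (1), cholesterol (0.678) and epithelial (0.984) lists completed the set. Interferon genes passed without Lo MTX replicate 3 (0.00233) and mesenchymal genes without Lo control replicate 3 (0.0352), while AKR1C3 was not called without Lo control replicates 1 or 2 or Lo MTX replicates 2 or 3 (0.065, 0.102, 0.1 and 0.0847). For the antigen presentation, NRF2 and epithelial lists the median, mean and test differed in sign.

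**Figure D3:**
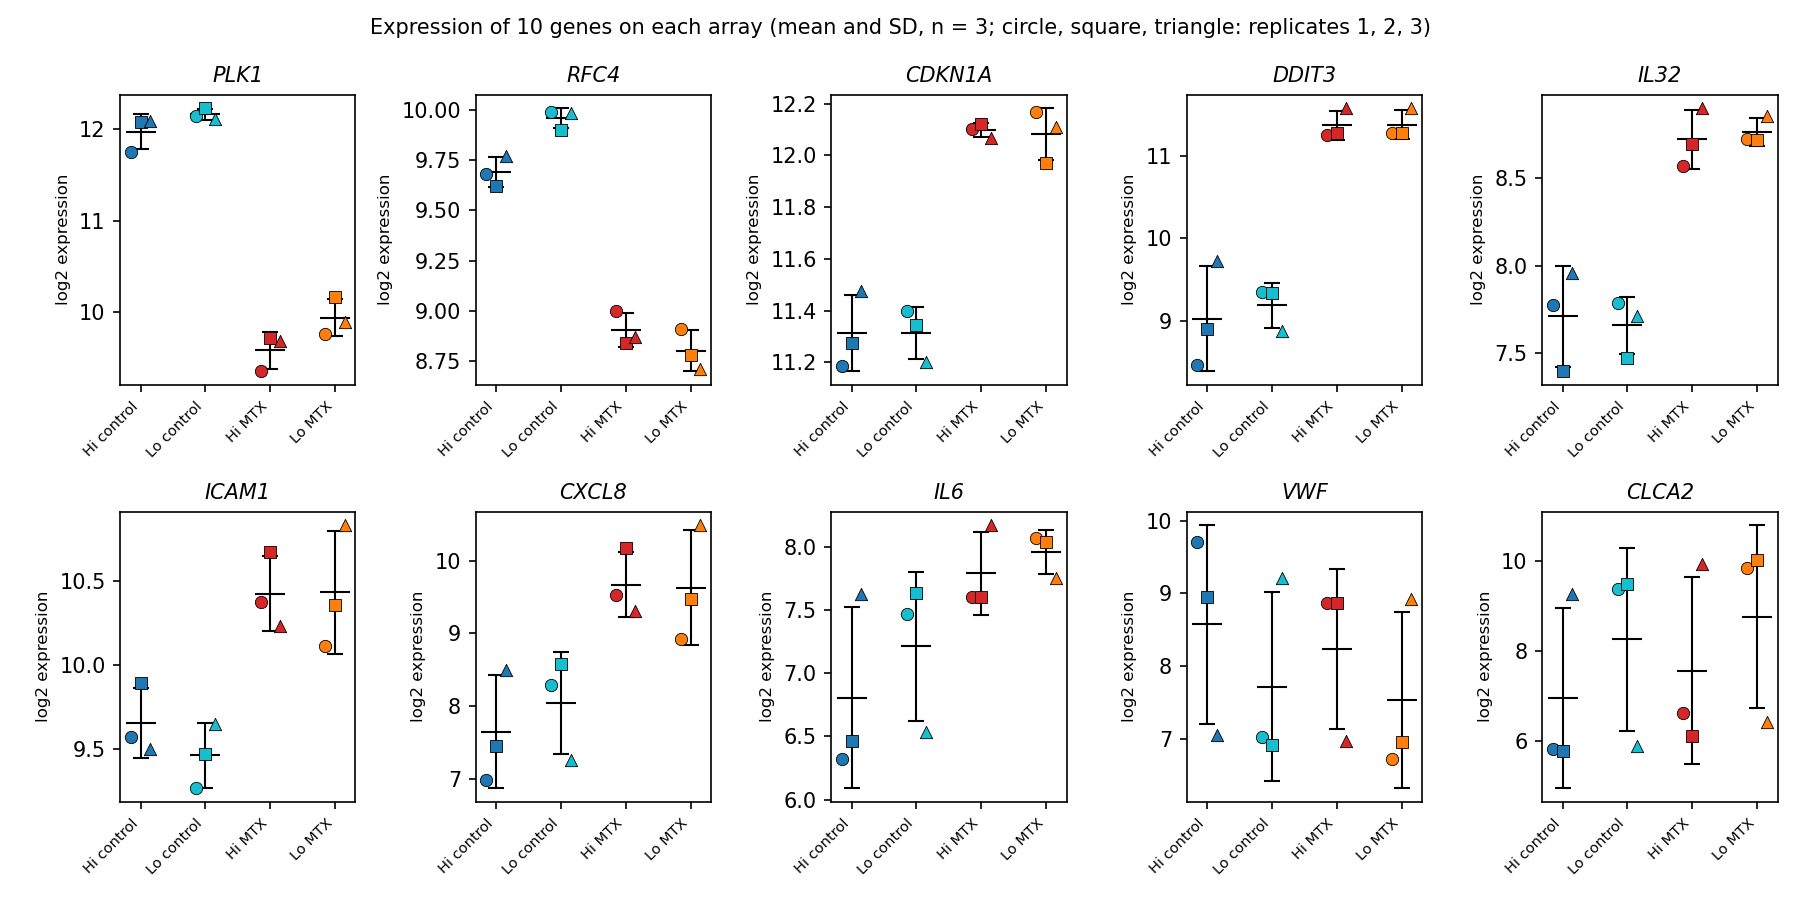
Log2 expression (y axes) of 10 genes on each array, by labelled group (x axes), with the mean and SD of 3 arrays in black and circle, square and triangle for replicates 1, 2 and 3. PLK1 and RFC4 were lower and CDKN1A, DDIT3 and IL32 higher on all MTX arrays than on all control arrays, while VWF and CLCA2 on the replicate 3 arrays lay at the level of the other medium label.

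With the groups as labelled, the MTX responses in both media overlapped closely. Of the called genes, 486 were higher and 426 lower in both media and 0 went in opposite directions, where independent lists would share 22.8 and 16.7. Among the 1495 genes called in either medium 1492 had the same sign in both. Across all 18417 genes the log2 changes correlated with Pearson's r of 0.908 and Spearman's rho of 0.753, over genes, which are not independent replicates. The 2 comparisons share no array. Each labelled medium did hold replicate 3 arrays that lay with the other medium label, and such mixing can make the 2 responses more alike. The correlation was lower without replicate 3, as given further below. It was also lower without any 1 array (0.83 to 0.903), so its fall does not show such mixing. PLK1, H2BC14, PRC1 and BUB1 were among the 5 largest falls, and C3, DDIT3, IL1RL1 and SAT1 among the 5 largest rises, in both. The shared genes numbered 542 without Hi control replicate 2, 2959 in the paired fit, and 1364, 30 and 179 without all arrays of replicate 3, 2 or 1. In the paired fit 2 genes, named after their values were seen, went in opposite directions: FPR2 (-0.23 in Hi and 0.23 in Lo cells, paired adjusted p = 0.0467 and 0.0498) and HLA-DQB1 (-0.29 and 0.28, paired adjusted p = 0.0236 and 0.0259). Their interaction had a paired adjusted p of 1.

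Averaged over media, MTX raised 1588 genes and lowered 1452, with 62 and 84 at least 2-fold. The larger side turned in the paired fit, with 5812 genes (2816 higher, 2996 lower), and without all arrays of replicate 3, with 4055 (1948 higher, 2107 lower). Without replicate 2 or 1 there were 783 and 1173, and with array medians subtracted 1786 were higher and 1266 lower. The interaction, which asks whether MTX acted differently in Lo and Hi cells, was called by limma for 0 genes, with 203 at an unadjusted p under 0.05 where chance gives 920.85, and for 0 genes without moderation and in the paired fit. CXCL8, called in Hi and not in Lo cells, is thus not shown to differ between them. Nor does a count of 0 show equal effects, since the replicate 3 arrays widen the spread within the labelled groups. By camera the interaction was below 0 for DNA replication and G1/S (median log2 difference -0.12, adjusted p = 7.69e-07), purine and pyrimidine synthesis (-0.06, adjusted p = 0.0468) and the unfolded protein response (-0.06, adjusted p = 0.0468). These gave adjusted p = 0.44, 0.963 and 0.869 with an estimated correlation. DNA replication did not pass without Hi control replicate 1 (0.218). Purine and pyrimidine synthesis did not pass without Hi control replicates 1 or 2, Hi MTX replicate 3, Lo control replicates 1 or 2 or Lo MTX replicate 3 (0.644, 0.124, 0.663, 0.101, 0.736 and 0.95). The unfolded protein list did not pass without Hi control replicate 2, Hi MTX replicates 1, 2 or 3, Lo control replicates 1 or 2 or Lo MTX replicate 3 (0.439, 0.0997, 0.0531, 0.078, 0.483, 0.589 and 0.539). The purine and pyrimidine and the unfolded protein lists also did not pass under further quantile normalization (0.196 and 0.201), over all probe sets (0.144 and 0.136), among the brighter genes (0.109 and 0.0931) or with the replicate block over all groups (0.0707 and 0.0594), and the former with array medians subtracted (0.0537). Lists that passed when 1 array was left out were folate genes without Hi control replicate 3 (0.0135) or Lo MTX replicate 2 (0.041), mitosis without Hi control replicate 1 (0.00205) or Hi MTX replicate 3 (0.00663), and epithelial markers without Lo control replicate 1 (0.0386). The p53 list passed without Hi control replicate 3, Hi MTX replicate 1, Lo control replicate 3 or Lo MTX replicate 3 (0.000148, 0.0329, 0.000238 and 0.0324), and the interferon list without Hi MTX replicate 3, Lo control replicate 2 or Lo MTX replicate 3 (3.12e-08, 0.032 and 2.75e-05). Endothelial markers passed without Hi control replicate 3, Hi MTX replicate 2 or Lo control replicate 3 (0.0016, 0.0199 and 0.00603), and hypoxia genes without Lo control replicate 3 (0.0143) or Lo MTX replicate 1 (0.0336). The median, mean and test of the interaction differed in sign for histones, leukocyte adhesion, ATF4 and cholesterol genes, which did not pass. Without all arrays of replicate 3 (n = 2 per group), camera with the preset correlation gave larger list differences. The interaction then passed for p53 targets (median -0.18, adjusted p = 1.63e-08), interferon genes (0.25, adjusted p = 1.19e-11) and cholesterol genes (0.17, adjusted p = 0.000431). Purine and pyrimidine synthesis did not pass there (adjusted p = 0.22). By limma the same fit had 9 genes with an interaction above 0 and 12 below. The latter included C3 (-1.71, adjusted p = 0.0133), IL1RL1 (-1.40, adjusted p = 0.0133) and SAT1 (-0.79, adjusted p = 0.0357), which with all arrays had -0.51, -0.39 and -0.17 (adjusted p = 1 for each).

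Between arrays labelled Lo and Hi in control cells, 0 genes were called by limma, and 361 had an unadjusted p under 0.05 where chance gives 920.85. The count without moderation was also 0. IL6 differed by 0.41 ± 0.34 on the log2 scale (Lo minus Hi, 95% interval -0.34 to 1.16), CXCL8 by 0.40 ± 0.47, PTGS2 by 0.44 ± 0.36, ICAM1 by -0.19 ± 0.18 and CDKN1A by 0.00 ± 0.09 (adjusted p = 1 for each). Without all arrays of replicate 3 the difference was 1.16 for IL6, 1.22 for CXCL8 and 1.26 for PTGS2 (adjusted p = 9e-05, 0.0156 and 0.000189, n = 2 per group). TYMS, SLC19A1, CCL2, VCAM1 and SELE differed by 0.14, 0.05, 0.18, 0.01 and 0.01, and FPGS by -0.00145. By camera the mitosis (median 0.24), DNA replication (0.18), purine and pyrimidine (0.11), p53 target (0.05) and unfolded protein (0.07) lists were above 0 and endothelial markers (-0.13) below. In that order the adjusted p was 1.29e-18, 3.39e-11, 5.76e-05, 0.0242, 0.00191 and 0.00798, with adjusted p = 0.279, 0.204, 0.664, 0.918, 0.602 and 0.963 with an estimated correlation. The purine and pyrimidine call was lost without Hi control replicate 1 (0.0509), and the unfolded protein call without Hi control replicate 2 or Lo control replicates 1 or 2 (0.146, 0.145 and 0.122). Without Hi control replicates 1 or 2 or Lo control replicates 1 or 2 the p53 list had 0.584, 0.21, 0.169 and 0.765 and the endothelial list 0.82, 0.135, 0.165 and 0.331. The p53 call was also lost under further quantile normalization (0.155), over all probe sets (0.0651) and among the brighter genes (0.199). The direction turned for p53 targets without all arrays of replicate 2 (median -0.01, adjusted p = 0.983) and for endothelial markers without those of replicate 1 (0.02, adjusted p = 0.849). The other lists did not pass with all arrays. Folate genes had a median of 0.04 (adjusted p = 0.0557) and passed without Hi control replicate 3 (0.0113), Hi MTX replicate 3 (0.0483) or Lo control replicate 1 (0.0193). Interferon genes passed without Hi control replicate 3 (0.00483) or Lo control replicate 3 (0.00668), and cholesterol genes without Hi control replicate 2 (0.0337) or Lo control replicate 1 (0.00363). Histones passed without Lo control replicate 1 (0.0144), and mesenchymal and hypoxia genes without Lo control replicate 3 (0.00285 and 0.0177). For cytokines, leukocyte adhesion, coagulation and adenosine genes the median, mean and test differed in sign.

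Replicates 1 and 2 alone, a choice made after the values were seen, gave 951 genes higher and 866 lower in the control arrays labelled Lo, with n = 2 per group. The genes named here were chosen after their values were seen. AMTN was 20.8-fold higher (4.38 ± 0.22), CLCA2 12.4-fold (3.63 ± 0.15), SPP1, the matrix protein osteopontin, 6.37-fold (2.67 ± 0.18) and IL1B 4.38-fold (2.13 ± 0.14). The endothelial genes CALCRL, MMRN1, VWF and KDR were 5.56-, 5.23-, 5.13- and 3.92-fold lower. In replicate 3 each went the other way, with log2 differences of -4.59 for AMTN, -3.35 for CLCA2, -2.63 for SPP1, -1.70 for IL1B, 2.89 for CALCRL, 2.54 for MMRN1, 2.15 for VWF and 1.76 for KDR. Of 36 interferon-stimulated genes 17 were higher in replicates 1 and 2, with XAF1 at 3.36-fold and IFI6 at 2.50-fold (list adjusted p = 2.99e-11, and adjusted p = 0.233 with an estimated correlation). Of 26 endothelial markers 10 were lower and 1 higher (adjusted p = 2.78e-11, and adjusted p = 0.359 with an estimated correlation). Hypoxia genes were above 0 by camera with the preset correlation (median 0.12, adjusted p = 0.0113).

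Between arrays labelled Lo and Hi under MTX, limma called 0 genes, with 205 at an unadjusted p under 0.05, and 0 without moderation. The mitosis (median 0.31) and interferon (0.18) lists were above 0 by camera (adjusted p = 1.39e-24 and 0.000431), with adjusted p = 0.185 and 0.963 with an estimated correlation. The interferon call was lost without Hi MTX replicates 1 or 2 or Lo MTX replicates 1 or 2 (0.48, 0.451, 0.28 and 0.337). The interferon median ran from 0.05 to 0.44 without 1 array, and the direction turned without all arrays of replicate 2 (-0.08, adjusted p = 0.455) or 1 (-0.05, adjusted p = 0.601). Lists that passed when 1 array was left out were purine and pyrimidine synthesis without Hi MTX replicate 3 (0.014) or Lo MTX replicate 3 (0.00197), and histones without Hi MTX replicate 2 (0.00265) or Lo MTX replicate 2 (0.000427). Endothelial markers passed without Hi MTX replicate 3 (0.000225) or Lo MTX replicate 3 (0.0112), and cholesterol and ATF4 genes without Hi MTX replicate 3 (0.00253 and 0.0475). For p53 targets, leukocyte adhesion, hypoxia, AP-1 and leukocyte marker genes, which did not pass, the median, mean and test differed in sign. Without replicate 3 there were 1005 genes higher and 459 lower, among them CLCA2 (3.56), SPP1 (3.08), XAF1 (1.91), VWF (-2.04) and CALCRL (-2.29) as log2 differences. In that fit 25 of the 36 interferon-stimulated genes were higher (adjusted p = 1.78e-24, and adjusted p = 0.233 with an estimated correlation). By camera with the preset correlation endothelial markers were also below 0 there (median -0.31, adjusted p = 2.31e-08). Mesenchymal, purine and pyrimidine, cholesterol, ATF4, NRF2 and hypoxia genes were above 0 (adjusted p = 8.06e-05, 0.000372, 0.00916, 0.0194, 0.0386 and 0.0448).

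The Lo minus Hi difference in control cells was set against the MTX effects across genes. It correlated with the MTX effect in Hi cells with r = 0.26, and with that in Lo cells with r = 0.0145. Unchanged groups simulated with independent arrays give 0.501 for shared Hi controls and -0.502 for shared Lo controls. The covariances were 0.00743 and 0.000409, against simulated values of 0.00984 and -0.00984. Part of each correlation may come from the shared control arrays, and splitting 3 controls leaves fewer than 2 on one side. Without replicate 3 the correlations were 0.396 and 0.143, where unchanged groups give 0.498 and -0.499, and the covariances 0.0263 and 0.00888, against 0.00617 and -0.00617 simulated. Leaving out Hi control replicate 3 gave 0.549 for the correlation with MTX in Hi cells, where unchanged groups give 0.599. The covariance was 0.0291 against 0.013 simulated. All simulated arrays were independent, whereas real control and MTX arrays of the same number correlated within a medium. The simulated values therefore do not hold for paired arrays and may lie too far from 0. No conclusion is drawn from the real values lying above or below them.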

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

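The tests of the first pattern, and the splits of the arrays for Lo minus Hi and for the interaction, were chosen after the results were seen. The pattern is that the arrays labelled replicate 3 stood with the other medium label in both treatments. The Lo minus Hi difference of replicate 3 correlated across genes between -0.764 and -0.519 with those of replicates 1 and 2, while differences of replicates 1 and 2, and of replicate 3 in control and MTX arrays, correlated between 0.56 and 0.794. For a batch shared by the replicate 3 arrays, the deviations of replicate 3 arrays of opposite medium and treatment correlated at -0.16 or lower. The pattern itself makes these correlations negative, which could hide a smaller batch effect, so this test cannot decide on a batch. An intensity trend is argued against, as the highest of the 8 correlations was -0.542 after removing it. An exchange of the Hi and Lo labels in 1 set of replicates remains a candidate explanation, with -0.519 as the highest of the correlations that it needs below 0, and these data cannot say which replicates would carry the right labels. A difference in culture state that ran against the label in 1 experiment was not tested and stays open.

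Lists whose MTX effect differed between Lo and Hi cells by camera's test of the interaction were DNA replication and G1/S (median log2 difference -0.122), purine and pyrimidine synthesis (-0.0647) and the unfolded protein response (-0.0592). None of these 3 held with an estimated correlation or by fry (fry adjusted p of 0.968, 0.98 and 0.98).

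Other splits of the arrays were counted for each comparison. For MTX in Hi and in Lo cells 1 of 10 splits gave as many genes as the real one (1229 and 1178 genes, highest other 0 in each), and 10 splits are too few for a share under 0.05. The pairs part as fully in 3 of the other splits, which also gave 0 genes. For MTX averaged over media 1 of 100 assignments gave as many (3040 genes, highest other 1), but these assignments were drawn without regard to the pairs. Of the 32 assignments that part every pair, a count added after the data were seen, 1 gave as many in the unpaired fit (3040, highest other 0) and 1 in the paired fit (5812, highest other 0). The share of 0.0312 is the smallest that 32 assignments can give, and the pairs were inferred from these same data. It argues against chance but does not exclude it. The other 31 assignments turn 1 to 5 of the 6 pairs. For Lo minus Hi in control and in MTX-treated cells and for the interaction the real count was 0, which every split matches by construction (10 of 10, 10 of 10 and 100 of 100), so these tell nothing about chance. The highest other splits for Lo minus Hi gave 906 and 564 genes, and in both the replicate 3 arrays of the media had changed sides, which points to a structure of the samples. The highest other assignment for the interaction gave 590 genes.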

How the results depend on the processing

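All settings that leave out every array of 1 replicate number, and the paired fit, were added after the data were seen. The directions of the 19 list calls and 93 gene calls for MTX held in every setting run. Of the list calls 19 held under further quantile normalization, under subtraction of array medians and in the paired fit, 16 under fry, 18 among the brighter genes and 0 with an estimated correlation. Leukocyte adhesion molecules for MTX in Hi cells passed only under fry (fry adjusted p = 0.0248). Of the 11 list calls for Lo minus Hi and the interaction fewer held: 8 under further quantile normalization, over all probe sets and among the brighter genes, 10 under subtraction of array medians, 9 with the replicate block over all groups, and 10, 5 and 4 without all arrays of replicate 3, 2 and 1. Under fry and with an estimated correlation 0 held. The brighter genes gained folate genes in control Lo minus Hi (adjusted p = 0.032) and endothelial markers in that under MTX (0.0482), and all probe sets gained purine and pyrimidine synthesis and adenosine genes for MTX in Hi cells (0.0492 each). Of the gene calls 92, 92 and 83 held under those 2 scalings and without moderation, but 22 without all arrays of replicate 2 and 52 without those of replicate 1. With the replicate block over all groups, where numbers of different media do not pair, MTX gave 1458 genes in Hi cells and 1361 in Lo cells, and the averaged effect 3290. The paired fit gave 3864, 3745 and 5812, with 2959 shared, and besides the IL6, PTGS2, CCL2 and CXCL8 calls and the mitosis list with an estimated correlation it changed 1 list call, hypoxia in Hi cells (adjusted p = 0.0174), and no other call of a named gene or list under camera. Its list tests were adjusted over fewer tests than in the main fit, so these list changes cannot be put down to the pairing alone.

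The counts for MTX in Hi cells, in Lo cells, averaged and shared varied with the pairing, array weights, thresholds and arrays below. A stricter limit lowers a count by itself, and the cause of the other changes was not tested. Array weights gave 2513, 3081, 4823 and 1767, an adjusted p under 0.01 gave 509, 544, 1637 and 407, and a fold of at least 1.5 gave 460, 457, 572 and 364. With only the compared groups Hi cells had 785 and the shared set 543. Without replicate 3 the counts were 2393, 2077, 4055 and 1364, without replicate 2 they were 30, 84, 783 and 30, and without replicate 1 225, 239, 1173 and 179. Of these, 4055 averaged and 1364 shared lie within 1.5 times of the counts with all arrays (3040 and 912), as do the averaged counts without 1 array. The fits without replicate 3, 2 or 1 leave out equally many arrays, so fewer arrays alone do not explain the lower counts without replicate 2 or 1. In those fits each group keeps its replicate 3 array, which lay with the other medium label, beside 1 other array. Leaving out 1 array gave 596 to 1527 in Hi cells, 708 to 1362 in Lo cells, 2336 to 3449 averaged and 542 to 961 shared. Lo minus Hi in control cells, in MTX-treated cells and the interaction had 0 genes in every other setting run and 1817, 1464 and 21 without replicate 3.

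The correlation of MTX effects between media was 0.792 over all probe sets, 0.836 with array weights, 0.786 without replicate 3 and 0.83 to 0.903 without 1 array. That of Lo minus Hi with MTX ran from 0.0942 to 0.549 in Hi and from -0.168 to 0.2 in Lo cells without 1 array, and was -0.361 in Lo cells without replicate 1. Lists whose test turned direction, passing before or after, are given here by their medians, cause not tested. They were interferon genes for MTX in Hi cells without Hi MTX replicate 3 (-0.291; -0.291 to 0.145 without 1 array) and purine and pyrimidine synthesis in the interaction without Lo MTX replicate 3 (0.00729; -0.144 to 0.00729 without 1 array). Without replicate 2 p53 targets in control Lo minus Hi came to -0.0123 and interferon genes under MTX to -0.0752. Without replicate 1 endothelial markers in control came to 0.0159 and interferon genes under MTX to -0.0469. Without replicate 3 hypoxia genes under MTX came to 0.11 and cholesterol genes in the interaction to 0.173. Medians of other lists near 0 also changed sign, such as p53 targets in control without Hi control replicate 1 (-0.00427). Signal over background was not available for the arrays, so changes of dim genes are limited by an unknown background.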

Other observations

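The tests in this part were chosen after the result was seen, and genes named here were chosen after their values were seen. In replicates 1 and 2 the control arrays labelled Lo, from cultures given vehicle, had lower levels of some endothelial genes and higher levels of some matrix genes. CCN2, a matricellular growth factor, was 3.10-fold higher, TGFBI 2.43-fold and CCN1 2.07-fold, and 11 of 29 mesenchymal and matrix genes were higher and 0 lower (list adjusted p = 4.84e-06, and adjusted p = 0.27 with an estimated correlation, n = 2 per group). EMCN, an endothelial sialomucin, was 3.42-fold lower and the junction molecule PECAM1 1.59-fold lower. Of 33 mitosis genes 16 were higher and 0 lower, the opposite side to the MTX effect, with CDC20 at 1.67-fold and CCNB1 at 1.63-fold. TNFAIP3, which restrains NF-kB, was 3.72-fold higher, IL6 2.23-fold and PTGS2 2.40-fold. In replicate 3 each went the other way, least for CCNB1. The log2 differences there were -1.5045 for CCN2, -1.22 for TGFBI, -0.95 for CCN1, 1.88 for EMCN, 0.70 for PECAM1, -0.44 for CDC20, -0.16 for CCNB1, -1.83 for TNFAIP3, -1.09 for IL6 and -1.19 for PTGS2.

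A hypothesis is that the state of the cells labelled Lo in replicates 1 and 2 shares part of the MTX response. To avoid shared control arrays, the control difference of 1 of these replicates was correlated across genes with MTX effects of pairs of another number. The 8 correlations ran from 0.141 to 0.363 with a median of 0.232, which argues against control arrays shared by the compared differences as the whole cause. The same 8 correlations for the difference in MTX arrays ran from 0.0972 to 0.295 with a median of 0.197, and 2 of them (0.0972 and 0.0974) lay below 0.1, within the band set for no resemblance. After intensity trends were removed the median for control arrays was 0.231, which argues against such a trend. If the labels of replicates 1 and 2 are right, a low folate supply may move part of the transcriptome the way MTX does, and if those of replicate 3 are right the direction turns, which these data cannot settle. Mitosis genes went the opposite way to MTX, as given above. Cells labelled Lo had been adapted to their medium, so other changes during adaptation cannot be told apart from an effect of folate supply.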
